A study of Gallus gallus with 6 samples.

How the data were processed

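Small RNA sequencing had been used to measure microRNAs (miRNAs, short RNAs that repress target transcripts) in abdominal fat of broiler chickens (Gallus gallus) at day 35. The 6 libraries fall into 3 of birds given 50 IU vitamin E and 3 controls, as the treatment label of each sample states. They come from a feeding study of 240 female chicks, 1 day old at the start, on 5 diets with 0, 20, 50, 75 or 100 IU of DL-α-tocopherol acetate, a synthetic form of vitamin E. The labels do not print the dose of the control diet beside its samples. They also do not say that the 3 libraries of a group came from separate birds, so p-values measure only the spread between these libraries, which may be technical.

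One table of 667 mature miRNAs was used, 551 with chicken miRNA names and 116 predicted ones whose names begin with novel_. The read counts deposited by the authors are whole numbers per miRNA with a different total in each library, per the file headers and the values. The TPM values deposited by the authors are the counts scaled to 1e+06 per library, with no length term; the largest deviation from that was 4.07e-10. The aligner, the counting rule, the miRNA reference and the genome build are not given in the sources used here, nor is the RNA extraction and library kit. No column of another sample was present, and no miRNA was at 0 in all 6 libraries. Totals were 5844435, 7062595 and 6096780 counts in the vitamin E libraries and 6666933, 5028671 and 7357204 in the controls. A count of 0 allows up to 3 counts, or 0.408 to 0.597 counts scaled to a library total of 1e+06 (CPM) depending on the library. Such limits and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

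The comparison of vitamin E with control was fitted to the counts with edgeR 4.0.16 in R 4.3.3, using TMM scaling factors, the filterByExpr filter by group with a minimum count of 10 and a minimum total of 15, and the robust quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over the 238 miRNAs that passed the filter (216 named, 22 predicted), with a threshold of 0.05; the other 429 were not tested. Normalised abundance is given as CPM on TMM-scaled library sizes, as mean ± SD over n = 3 libraries per group, and each log2 fold change is vitamin E over control with its standard error (SE). The biological coefficient of variation was 0.441.

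Lists of miRNAs by function and by tissue (18 in all) were written before the data were examined. A list member matched a mature miRNA by its name without the species prefix and arm. The 14 lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it, and Benjamini-Hochberg adjustment over the 14 lists. Members were also adjusted over the list alone. For 8 measures of library composition, the groups were compared by a two-sided exact permutation test over 20 relabellings, in which the smallest possible p is 0.1. Intervals have a confidence level of 95%.

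The miRNAs named singly were chosen by a rule written before the data were examined. It takes every miRNA past the threshold, the 8 with the smallest p in each direction whether or not they passed, and the 8 most abundant. From each list it adds the most abundant member and the one with the smallest p, with up to 2 further members in order of p. miR-375, the 1 lower member of its list, fell outside this rule, as did miRNAs named only for gene position. Others named in the closing parts were chosen after their values were seen. The chicken gene table of assembly GRCg7b served only for which miRNA genes overlap or lie within 10 kb of each other; its positions are not printed, because the build of the deposited table is not stated.

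In total, 21 alternative fits and 2 other thresholds were run on the comparison. The 18 planned fits cover other scaling factors, no filter and a stricter filter of 10 CPM, DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, each library left out in turn, and named miRNAs only. The other 3 were chosen after values had been seen: edgeR without robust estimation, limma-voom with a weight per group, and miR-219a and miR-219b, which have identical counts, counted once. A planned merging of precursors was not run, because no mature miRNA was listed more than once. The fit written down beforehand was kept as the reported one throughout. In the closing parts, 9 tests of explanations are given, 5 set down before and 4 after the result was seen. How the test of nervous tissue and those of neighbouring genes decide was changed afterwards, as stated where they are reported. For the latter, families known to have alike sequences (such as miR-17 with miR-20, miR-15 with miR-16 and miR-200 with miR-429) were grouped by name, since no miRNA sequences were used here.

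The procedure was tested on simulated data with the means, dispersions and depths of these libraries: 20 simulations of the comparison of vitamin E with control, each with 238 miRNAs of which 40 were changed. The edgeR quasi-likelihood test called 19.6% of miRNAs changed 2-fold, 75.0% of those changed 4-fold and 95.8% of those changed 8-fold, and 6.38% of its calls were false. DESeq2 called more of the 2-fold changes (30.0%), with 10.6% of its calls false. In these simulations each miRNA had the same dispersion in both groups, whereas in the data control libraries spread more (median SD ratio 1.73). With 40 of 238 changed, the shares called may not carry over to a comparison in which few miRNAs change. In 20 further simulations over the same 238 miRNAs with the let-7 list raised 4-fold, camera called that list in 20, and 4 of 260 tests of the other lists were called. Each miRNA was drawn independently there, so camera's preset correlation was not tested for lists whose members vary together. In the data the estimated correlation was 0.079 for the neural and endocrine list and 0.19 for the striated muscle list.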

Results

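miRNA abundance was compared between abdominal fat of broilers given 50 IU vitamin E and of controls at day 35, to ask which miRNAs differ with the supplement in a study of fat deposition. Each group had 3 libraries, with 5844435 to 7062595 counts in the vitamin E libraries and 5028671 to 7357204 in the controls. The mean depth was 6334603 ± 642961 counts with vitamin E and 6350936 ± 1195996 in control (SD, n = 3; exact permutation p = 1, two-sided).

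A small number of miRNAs made up most of each library. The 10 most abundant took 67.0% ± 0.56 of the counts with vitamin E and 68.4% ± 3.64 in control (SD, n = 3; exact permutation p = 0.8). miR-26a-5p was the most abundant, at 148908 ± 8629 CPM with vitamin E and 180279 ± 25649 in control (log2 fold change -0.28, SE 0.18). miR-10a-5p, encoded in a Hox gene cluster, followed with 0.21 (SE 0.22; 0.046 without vitamin E 3), and the predicted miRNA novel_1 stood at 80517 ± 9965 against 114759 ± 16636 CPM. Among the remaining members of the 8 most abundant, log2 fold changes were -0.01 for miR-22-3p, -0.12 for miR-199-3p, -0.01 for miR-148a-3p, -0.28 for miR-10b-5p and -0.13 for let-7f-5p. None of the 8 passed the edgeR quasi-likelihood test, and the signs of miR-22-3p and miR-148a-3p turned when libraries were scaled by their totals alone. Without control 3, miR-199-3p was at 0.095 and miR-148a-3p at 0.15. Without control 1, let-7f-5p was at 0.036, miR-22-3p at 0.062 and miR-10b-5p at -0.15. The let-7 family held 8.44% ± 1.01 and 7.76% ± 1.19 of the counts (exact permutation p = 0.5). None of the 8 composition measures reached a permutation p below 0.1, the smallest this design allows; the share of the most abundant miRNA and that of all predicted miRNAs stood at that limit (Benjamini-Hochberg adjusted permutation p = 0.4 for both).

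miR-9-5p, a miRNA abundant in the nervous system, was the 1 miRNA that passed the threshold, and it rose with vitamin E. It stood at 148 ± 8.81 CPM with vitamin E and 31.5 ± 9.44 CPM in control (SD, n = 3), a 4.71-fold difference. All 3 vitamin E libraries lay above all 3 controls, at 143 to 158 against 25.5 to 42.4 CPM. The log2 fold change was 2.24 (SE 0.35, 95% interval 1.44 to 3.03), with an adjusted p of 0.0396 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 238 miRNAs. No miRNA fell past the threshold. Genes of miR-9 overlap genes of miR-9b in assembly GRCg7b, and how shared reads were counted is not given in the sources used here, so the identity of the reads is uncertain. The call was lost with upper-quartile scaling (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0788, log2 fold change 2.14) and when any 1 library other than control 1 was left out. In those 5 fits of the edgeR quasi-likelihood test the Benjamini-Hochberg adjusted p ran from 0.0867 to 0.380, while the log2 fold change over all 6 such fits stayed between 2.06 and 2.43.

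The opposite arm of the same hairpin, miR-9-3p, stood at 7.73 ± 0.78 against 1.12 ± 0.64 CPM, with a log2 fold change of 2.73 (SE 0.56) that did not pass the threshold in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0865). miR-34b-5p, of a family induced by p53, had 15, 24 and 14 counts with vitamin E and 0, 2 and 2 in control. Its ratio was 12.3 on summed counts divided by TMM-scaled library sizes, with an exact 95% counting interval of 4.54 to 46.9. miR-34b-5p did not pass either (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0865). miR-34c-5p, from the gene next to miR-34b in assembly GRCg7b, stood at 12.6 ± 3.62 against 4.02 ± 2.11 CPM. miR-193b-3p, from a miRNA cluster studied in brown fat differentiation, stood at 322 ± 107 against 115 ± 19.8 CPM, a log2 fold change of 1.48 (SE 0.34). The remaining miRNAs with the smallest p on the higher side were miR-124c-5p at 1.94, miR-6606-5p at 1.89 and miR-124a-3p at 1.45 on the log2 scale. Adjusted p for these and for miR-34c-5p and miR-193b-3p ran from 0.138 to 0.335 (edgeR quasi-likelihood, Benjamini-Hochberg).

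On the lower side none of the 8 miRNAs with the smallest p passed the threshold. miR-122-5p, the dominant miRNA of liver, stood at 6.07 ± 1.10 CPM with vitamin E and 16.1 ± 4.21 in control, a log2 fold change of -1.40 (SE 0.43). A miR-122 gene overlaps a gene of miR-122b in GRCg7b, so the identity of the miR-122-5p reads is likewise uncertain. miR-205b, of an epithelial miRNA family, had -2.24 (SE 0.71), with one control library at 230 CPM and the others at 45.3 and 48.6. miR-128-3p, reported to restrain fat cell differentiation, stood at 3430 ± 597 against 7772 ± 5304 CPM, and its control libraries ranged from 3277 to 13623. Log2 fold changes were -1.55 for miR-1416-5p, -0.51 for novel_1, -1.86 for novel_116, -1.21 for miR-20b-3p and -1.94 for miR-3525. Several of these values rested on 1 control library: without control 1 they were -0.56 for miR-3525, -0.61 for miR-128-3p and -0.94 for miR-1416-5p, and without control 2 it was -1.05 for miR-205b. Adjusted p on this side ran from 0.325 to 0.605 (edgeR quasi-likelihood, Benjamini-Hochberg).

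**Figure D1:**
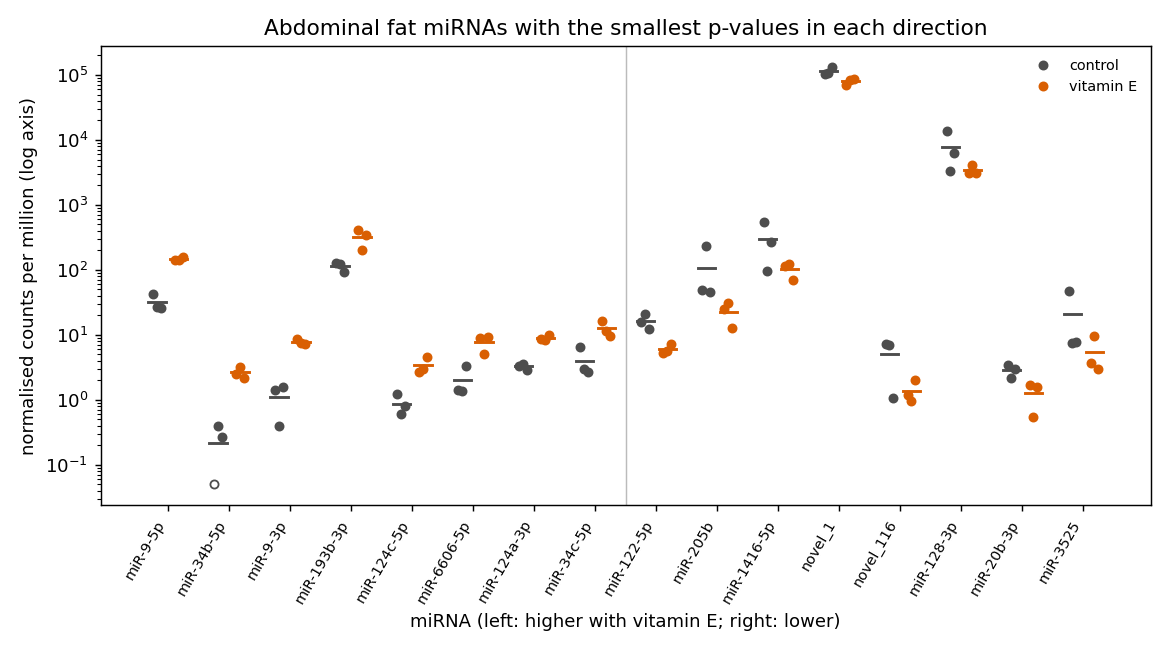
Normalised abundance in CPM (log axis) of the 8 miRNAs with the smallest p in each direction, higher with vitamin E on the left and lower on the right. Points are libraries, 3 per group, horizontal lines are group means, and the open circle marks the count of 0 of miR-34b-5p in control 1, placed below the lowest value because a log axis has no 0; miR-9-5p, at 148 against 31.5 CPM, is the 1 that passed the threshold.

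Of the 238 tested miRNAs, 18 had an unadjusted p under 0.05, 12 higher and 6 lower with vitamin E, where 11.9 would be expected with no effect. At an adjusted threshold of 0.1, 3 passed the edgeR quasi-likelihood test: miR-9-5p, miR-9-3p and miR-34b-5p. The 2 groups did not overlap for 33 miRNAs (13.9%, 21 higher and 12 lower), where chance gives 10%, or 23.8.

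**Figure D2:**
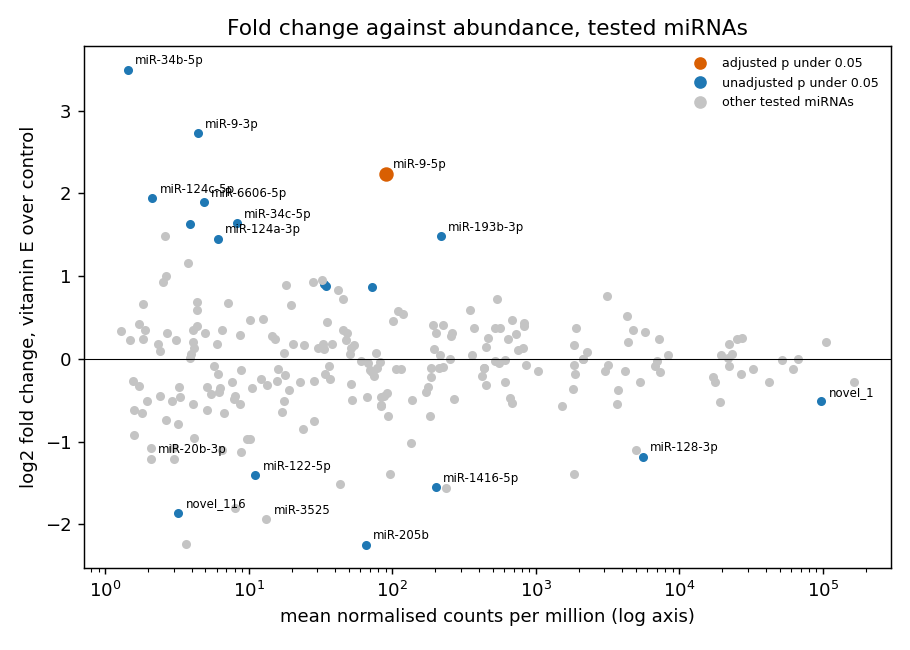
Log2 fold change, vitamin E over control, of each of the 238 tested miRNAs against mean normalised abundance in CPM (log axis). miR-9-5p (orange) passed an adjusted p of 0.05, a further 17 (blue) had only an unadjusted p under 0.05, and named points are those with the smallest p in each direction.

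Neural and endocrine miRNAs stood higher with vitamin E as a group in camera at its preset correlation (adjusted p = 5.96e-05, Benjamini-Hochberg over 14 lists), but not with an estimated correlation (adjusted p = 0.193). Of 5 tested members, 4 were higher (both arms of miR-9, miR-124c-5p and miR-124a-3p) and 1 was lower, miR-375, a miRNA of pancreatic islet and other endocrine cells, at -1.07. miR-9-5p passed over all miRNAs tested, and 4 members passed adjusted over the list alone. Together the members summed to 170 ± 10.6 CPM with vitamin E and 39.6 ± 8.94 in control, most of it miR-9-5p. The list passed in fry (adjusted p = 0.00759), and fry lost it in 4 of the 6 fits with a library left out, with adjusted p from 0.0509 to 0.0987. The 4 higher members come from 2 gene groups, since the miR-9 arms share a hairpin and the miR-124a and miR-124c genes overlap in GRCg7b, so miR-124a and miR-124c are reported as uncertain. The same holds for the miR-9 arms.

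The striated muscle list passed in camera at its preset correlation (adjusted p = 0.0384, Benjamini-Hochberg), but not with an estimated correlation (adjusted p = 0.463) or in fry (adjusted p = 0.196). All 5 of 5 tested members were higher and none passed singly. Members miR-133a, miR-133b and miR-133c share a family number, and how shared reads were counted is not given in the sources used here. The values of miR-133b and miR-133c-3p, the rarer ones, are therefore reported as uncertain. miR-133b stood at 5.88 ± 1.73 against 1.88 ± 1.06 CPM (log2 fold change 1.63, SE 0.58), miR-133c-3p at 0.89 and miR-1a-3p at 1.01 (0.58 without vitamin E 2). miR-133a-3p, the most abundant member, was level at 363 ± 140 against 351 ± 117 CPM, and its log2 fold change of 0.05 turned negative with median-of-ratios and upper-quartile scaling. Leaving out any library but vitamin E 1 ended the camera call, with adjusted p from 0.0656 to 0.343.

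Among the 17 tested members of the oxidative stress and vitamin E list, 11 were higher and 6 lower. Not all are separate loci in GRCg7b: the miR-200a, miR-200b and miR-429 genes are neighbours, as are those of miR-34b and miR-34c. None passed over all miRNAs tested, and 1, miR-34b-5p, passed adjusted over the list alone. miR-21-5p, its most abundant member, had a log2 fold change of 0.18 (0.054 without control 1), and miR-122-5p had -1.40. Camera gave an adjusted p of 0.209 and fry 0.188 (Benjamini-Hochberg). In fry's mixed test, which asks for change in either direction and does not compare the list with other miRNAs, the adjusted p was 0.00218 for this list, and the same for the neural and endocrine list. With the reported scaling and all libraries no other list passed it, and with median-of-ratios factors the lipid metabolism list did too (adjusted p = 0.0429). The oxidative stress list passed camera in 1 of the 6 fits with a library left out, that without vitamin E 1 (camera adjusted p = 0.0397), and there the camera adjusted p was 0.334 with an estimated correlation.

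Lists tied to fat cells did not pass. Of 20 tested members of the adipogenesis promoting list, 9 were higher and 11 lower, with miR-30c-2-3p having the smallest p (log2 fold change -0.48, and -0.26 without control 1) and miR-148a-3p the highest abundance. Of 19 tested adipogenesis inhibiting members, 10 were higher and 9 lower; miR-128-3p had the smallest p, and miR-22-5p stood at 44.7 ± 9.51 against 24.2 ± 5.75 CPM. The lipid metabolism list had 7 higher and 5 lower of 12, led by miR-122-5p. Camera adjusted p was 0.963 for all 3 lists, and 0 of their members passed adjusted over the list alone. The medians of the inhibiting and lipid lists, 0.06 and 0.10, had the opposite sign to their means, -0.03 and -0.08. Signs in these lists depended on scaling: with library totals alone, 14 of the 20 promoting members were higher, and with upper-quartile factors 6.

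Families and other tissue markers likewise gave no list past the threshold. The let-7 family had 4 higher and 9 lower of 13, with let-7b at 0.52 (0.27 without vitamin E 1). The miR-17-92 group had 6 and 6, with miR-92-3p at -0.22 (0.51 without control 1). The miR-30 family had 5 and 4, with miR-30e-5p at 0.25 (-0.059 without control 3). The miR-29 family had 1 and 2, with miR-29b-3p at 0.17 (-0.016 without control 1) and miR-29c-3p at -0.11. miR-29a-3p and miR-29c-3p had nearly equal values (417 and 418 CPM with vitamin E) and are reported as uncertain, since near-identical sequences can share reads. Epithelial markers had 7 higher and 2 lower of 9, with miR-200a, miR-200b and miR-429 from neighbouring genes in GRCg7b. These are also members of the oxidative stress and vitamin E list. In the epithelial list miR-200b-3p stood at 93.6 ± 15.1 against 51.4 ± 4.75 CPM and miR-200a-3p at 141 ± 19.6 against 97.0 ± 23.7 (log2 fold change 0.54, and 0.32 without control 1), while miR-205b was lower (camera adjusted p = 0.209). Leukocyte markers had 4 higher and 7 lower of 11, with miR-146a-3p at -0.69 and miR-146c-5p at -0.09; with library totals alone 8 were higher. In the smooth muscle and stromal list 2 of 3 were higher, miR-199-5p at 0.32 among them (0.087 without vitamin E 3). Among 3 erythroid markers, miR-451, matured in red cell precursors, stood at 3967 ± 1054 against 2350 ± 931 CPM (log2 fold change 0.76, and 0.43 without control 3), while miR-144-5p and miR-144-3p had log2 fold changes of -0.42 and -0.04 (with library totals alone miR-144-3p was above 0, and without control 1 miR-144-5p was at 0.09). Median and mean differed in sign for the erythroid list (-0.04 and 0.10) and the miR-30 family (0.01 and -0.12), and camera placed the miR-17-92 group upward against a mean of -0.14. Camera adjusted p for these lists other than the epithelial one was 0.963.

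Other tissue markers had fewer than 3 tested members and no set test. miR-126-3p, the endothelial miRNA, had a log2 fold change of -0.18 (-0.077 without control 1). The liver list was represented by miR-122-5p at -1.40, which passed when adjusted over that list of 1 and not over all miRNAs. Both intestinal markers were lower, miR-215-5p at -1.56 and miR-194 at -0.75 (-0.24 without control 2). For miR-215-5p 1 control library stood at 863 CPM and the other 2 at 110 and 84.3; without that library (control 2) its log2 fold change was 0.30. The gonad marker miR-202 had no tested row, with 1 to 7 counts per library.

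**Figure D3:**
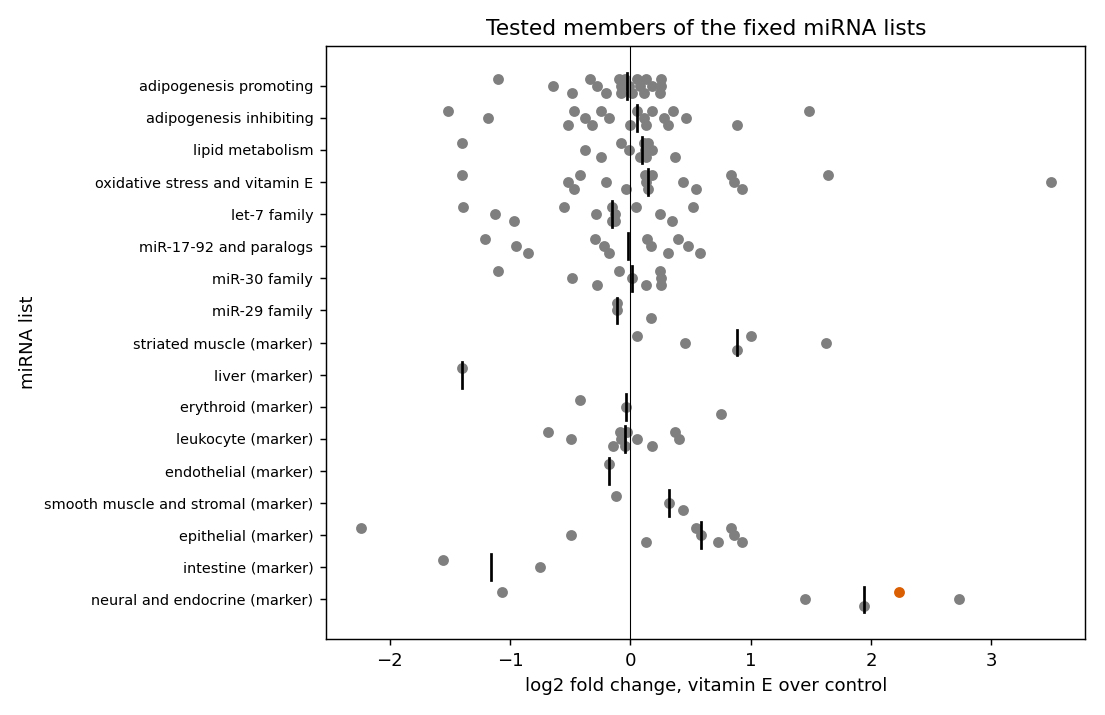
Log2 fold change, vitamin E over control, of the tested members of each list; points are miRNAs, black bars are list medians and the orange point passed an adjusted p of 0.05 over all miRNAs. The neural and endocrine list has 4 of 5 points above 0; the striated muscle list has 5 of 5 with the scaling shown, and 4 of 5 with median-of-ratios or upper-quartile factors.

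Control libraries lay farther apart than vitamin E libraries. Pairwise Pearson correlations of log2 CPM over the tested miRNAs were 0.980 to 0.988 within vitamin E, 0.960 to 0.970 within control and 0.967 to 0.980 between groups. The first principal component (32.9% of variance) placed control 1 and control 2 at opposite ends, and no component of the first 3 parted the groups. No pair of libraries was within sampling noise of another, with chi-square per degree of freedom of at least 405.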

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

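The alternatives without robust estimation, with a weight per group and with miR-219a and miR-219b counted once were chosen after values had been seen. The 1 miRNA past the threshold, miR-9-5p, was called in 15 of 21 alternative fits, with the smallest p in 20 of them and a log2 fold change between 2.06 and 2.43 (adjusted p 3.80e-07 to 0.380 over these fits, each with Benjamini-Hochberg adjustment). Upper-quartile factors gave 0 calls (0 higher) in edgeR; log2 fold change and SE were 2.24 and 0.35 before and 2.14 and 0.35 after, and 18 miRNAs had an unadjusted p under 0.05. Without the low-count filter 8 were called (4 higher, 4 lower) among 667, with DESeq2 3 (3 higher), with the edgeR likelihood ratio test 4 (4 higher) and with limma on log2(TPM + 1) 3 (3 higher). An adjusted threshold of 0.1 gave 3 (3 higher), and an unadjusted p under 0.05 with an absolute log2 change of at least 1 gave 14 (9 higher, 5 lower). Leaving out 1 library gave 0 to 1 calls (0 to 1 higher, 0 lower); with 11 to 31 unadjusted p under 0.05, miR-9-5p was called only without control 1, and fewer libraries mean less power. The cause of the differences between these fits was not tested. miR-9-3p was called in 5 of the 21 fits, miR-34b-5p and miR-193b-3p in 4 each, miR-205b in 2, and miR-128-3p, miR-1416-5p and novel_171 in 1, that without the filter. Scaling by totals alone shifted log2 fold changes by a median of 0.107 over miRNAs, and the limma fits on TPM by medians of 0.129 and 0.132.

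The replicate numbers 1 to 3 are shared by the groups, but same-numbered libraries did not deviate together (correlations of deviations -0.16, 0.05 and -0.02), and not every library correlated best with its own number. With the replicate number as a block 5 miRNAs were called, 4 higher and 1 lower (miR-205b). The block left the 2 list calls of camera at its preset correlation as they were, but ended the 2 of fry's mixed test (adjusted p 0.0591 for the oxidative stress and the neural and endocrine lists). With an estimated correlation neither camera call held under the block (camera adjusted p 0.578 for the neural and endocrine list and 0.715 for striated muscle).

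Of the lists, 2 passed with camera at its preset correlation. With an estimated correlation 0 passed, and with fry 1, the neural and endocrine list. Leaving out 1 library gave 1 to 4 lists in camera at the preset correlation; the neural and endocrine list passed in each of these 6 fits, and without vitamin E 1 the striated muscle, oxidative stress and epithelial lists passed too. With an estimated correlation none of these calls held: adjusted p was 0.242 to 0.728 for the neural and endocrine list over the 6 fits and, without vitamin E 1, 0.242, 0.334 and 0.419 for the other 3. The oxidative stress and epithelial lists share miR-200a, miR-200b and miR-429, so their calls are not independent of each other. Fry lost the neural and endocrine list in 4 of the 6 fits (adjusted p 0.0509 without vitamin E 2, 0.0697 without vitamin E 3, 0.0647 without control 1 and 0.0987 without control 3). Its mixed test called the neural and endocrine and the oxidative stress lists in all 6 (adjusted p 0.00137 to 0.0345), and also striated muscle without vitamin E 1 (0.00643), miR-17-92 without control 2 (0.00945), and lipid metabolism (0.0238) and epithelial (0.0320) without control 3. The top-10 share of counts differed by -1.45 percentage points, and by -0.04 with named miRNAs only.

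The count that follows leaves out the further list members named in order of p, such as miR-144-5p and miR-144-3p, whose signs also turned in some fits. Over the other 39 miRNAs named by rule, 44 of the values refitted turned sign, all for uncalled miRNAs. With library totals alone these were miR-22-3p 0.11, miR-148a-3p 0.070 and miR-146c-5p 0.018. With log2(TPM + 1) they were miR-22-3p 0.12, miR-199-3p 0.027, miR-148a-3p 0.11, let-7f-5p 0.00031, miR-92-3p 0.13, miR-29c-3p 0.0031 and miR-146c-5p 0.075. With log2(TPM + 0.1) they were miR-22-3p 0.12, miR-199-3p 0.027, miR-148a-3p 0.11, let-7f-5p 0.00031, miR-92-3p 0.13, miR-29c-3p 0.0032 and miR-146c-5p 0.075. With limma-voom they were miR-22-3p 0.014 and miR-92-3p 0.027, and with a weight per group miR-22-3p 0.014 and miR-92-3p 0.027. With the block they were miR-22-3p 0.010, miR-148a-3p 0.00081 and miR-92-3p 0.040. Without the filter miR-22-3p was at 0.024, and with identical miRNAs counted once at 0.0010. miR-133a-3p was at -0.0012 with median-of-ratios factors, -0.032 with upper-quartile factors and -0.040 with the stricter filter. With 1 library left out, values ran from -0.17 to 0.062 for miR-22-3p, -0.30 to 0.10 for miR-199-3p, -0.28 to 0.15 for miR-148a-3p, -0.29 to 0.036 for let-7f-5p, -0.54 to 0.51 for miR-92-3p, -0.059 to 0.58 for miR-30e-5p, -0.016 to 0.38 for miR-29b-3p, -0.31 to 0.27 for miR-133a-3p, -0.33 to 0.22 for miR-146c-5p and -2.03 to 0.30 for miR-215-5p. The cause of these turns was not tested. Without a turn, they ran from 0.046 to 0.35 for miR-10a-5p, 0.054 to 0.26 for miR-21-5p, 0.087 to 0.53 for miR-199-5p, -0.52 to -0.15 for miR-10b-5p and -0.33 to -0.077 for miR-126-3p. Counts of 0 to 2 in control limit miR-34b-5p, whose log2 fold change ranged from 1.62 with log2(TPM + 1) to 3.98.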

Other observations

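The test of miR-9-3p and miR-124 under other scalings, both tests on the spread of control libraries and the test of neighbours without related families were chosen after the result was seen, and all 3 patterns weighed here were noticed in these same data.

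Both arms of miR-9 stood higher with vitamin E, and over the other hairpins the arms showed no relation that could be detected. Over 51 hairpins with both arms tested and miR-9 left out, the log2 fold changes of the arms had a Pearson r of 0.016 (permutation p = 0.91) and a Spearman rho of 0.065 (permutation p = 0.64), and 28 had the same sign. With miR-9 included, r was 0.333 (permutation p = 0.02) and rho 0.118 (permutation p = 0.4), so r rested on miR-9. These are correlations across miRNAs, which are not independent replicates. Some hairpins had arms alike, such as miR-200b at 0.93 (5p) and 0.86 (3p), and others apart, such as miR-20b at 0.58 and -1.21; none of these arms passed the threshold.

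miR-9 and miR-124 stood higher in all 3 vitamin E libraries than in all 3 controls. Scaling as the cause is argued against: the lowest log2 fold change over median-of-ratios, upper-quartile and total-count scaling was 2.14 for miR-9-5p (SE 0.35) and 1.37 among miR-9-3p, miR-124a-3p and miR-124c-5p (SE 0.39), although upper-quartile factors ended the call of miR-9-5p. Differences in dissection or between birds were not tested for this pattern and stay open. RNA from nervous tissue in the fat samples may be a source. On the first test of it, set before the value was seen, 5 other nervous-system miRNAs had a median of 0.0028 (SD 0.30), under the bound of 1 and so against this source; miR-219b was then removed as a copy of miR-219a, and a condition was added, after that result, that at least 3 members stand below miR-9-5p in control. The reason is that miR-219a and miR-218-5p, at 2124 and 497 CPM in control, would hide a small added share; with the change the median of 4 was 0.105 (SD 0.34), only 2 were low enough (miR-383-5p at 0.48, which was at 0.013 without vitamin E 2, and miR-137-3p at 0.21, which was at -0.09 without control 1 and -0.07 without control 2), and nervous tissue and a response to vitamin E cannot be told apart here, though neither of those 2 reached the bound. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 1 call and the highest other gave 0, which is too few splits for a share under 0.05.

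Control libraries spread more than vitamin E libraries: the median ratio of their SDs of log2 CPM was 1.73, and the SD was larger in control for 176 of 238 miRNAs (73.9%). Depth as the cause is argued against, since thinning every library to 5028671 counts left the ratio at 1.71 ± 0.04 (SD over 20 thinnings). A single odd control library as the only cause is argued against by the closest control pair, control 2 with control 3. That pair lay 1.31 ± 0.10 times as far apart as the farthest vitamin E pair (bootstrap SD). Control 1 still lay farthest from every other library, at mean absolute log2 differences of 0.799 to 0.886. Pairs without control 1 reached at most 0.762 (vitamin E 3 with control 2). A larger part of control 1 in the spread therefore stays open. Of 10 splits, only the real one had a ratio as large, the highest other being 1.49, and with 10 splits no share under 0.05 can be had. Differences in dissection or between birds, and a narrower response on the supplement, stay open and were not tested.

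miRNAs whose genes lie within 10 kb of each other in GRCg7b may be transcribed together, and the 49 neighbour pairs differed by 0.443 in log2 fold change on average, against 0.611 for random pairs of like abundance (one-sided permutation p = 0.012, 10000 draws). Without pairs of the same family number, 35 pairs differed by 0.434 against 0.594 (permutation p = 0.035), which was first read as evidence against reads shared between near-identical sequences. That set still held related families, such as miR-17-5p with miR-20a-5p and miR-200b-3p with miR-429-3p; without these, 16 pairs differed by 0.570 against 0.574 (permutation p = 0.52). The closeness was thus seen only with related miRNAs included. Pairs were removed by family name without comparing sequences, and some joined a 5p with a 3p arm, such as miR-15b-5p with miR-16-2-3p. Their removal therefore cannot decide on shared reads. Shared transcription and shared reads cannot be told apart here, with 16 unrelated pairs, 6 of them with miR-92-3p. Pairs of one cluster share members, so the smaller p-values are likely too small.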
